A study of Mus musculus with 6 samples.

How the data were processed

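RNA was measured in 6 libraries of mouse spleen CD4+ T cells (strain C57BL/6J), 3 labelled medium alone and 3 labelled with CpdA. Per the labels' protocols, cells were activated with antibodies to CD3 and CD28 for 2 days with or without the compound, RNA was isolated with Trizol, and 1 µg of RNA per library was made into cDNA libraries with an NEBNext Ultra RNA kit. The dose in the labels is 20 with a unit read here as µM, because it is written as "µm". Groups were taken from the labels alone. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, and the vehicle given to the medium group is not given in the sources used here.

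The deposited table holds raw read counts per gene for each library, per the file headers, with no normalization. It also holds FPKM values that the authors computed: the count divided by the deposited gene length in kilobases and by the library's total count (as CPM does) gives back every deposited FPKM within a relative difference of 1.86e-07. The submitters' processing notes name CASAVA 1.8 and the builds GRCm38 and mm10. The aligner, the counter, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may have been divided in ways that cannot be checked. The table lists 21139 genes, of which 0 have a count of 0 in all 6 libraries, and the lowest summed count is 1. Of the gene identifiers, 20917 were found in a GENCODE annotation of GRCm38, and 99.97% of those overlapped their position there. There were 0 columns of per-sample values that could not be tied to a sample.

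All tests were run on the deposited counts in R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, robust dispersions and no covariates. Genes were kept by filterByExpr with its minimum count of 10 in enough libraries and minimum total of 15, which left 13507 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Fold changes are log2 values of CpdA over medium with their standard errors (SE). Levels are CPM, scaled by the library total, given as mean ± SD over 3 libraries. Library totals ran from 20247761 to 25952169 counts, and a count of 0 in one library allows up to 0.148 CPM at the lowest depth (3 counts, for counting error only). The 28 pathway lists and 12 cell type marker lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 28 lists. Camera asks whether a list moved more than the other genes. The same test with a correlation estimated for each list was run beside it, as were camera on ranks and fry, which asks only whether a list's genes moved on balance one way. Marker lists were summed per library and compared with an exact two-sided permutation test, for which 0.1 is the smallest p that 3 libraries against 3 can give. The p-values were then adjusted over the 12 lists.

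Genes named in the text follow a rule fixed before the data were examined. Part (a) takes the 12 highest and 12 lowest fold changes among changed genes above the median expression whose groups do not overlap, leaving out pseudogenes, ribosomal protein genes, mitochondrial genes, receptor segments and clone names. Part (b) takes up to 4 changed members with the smallest p from each list that was called or had at least 2 changed members. Part (c) is a fixed set of genes given whether changed or not. Il5, Il6, Il9, Nfil3 and Slc16a1 lie outside it and were chosen after their values were seen. The same holds for the markers named and the genes named for the families in the closing section, except Cd4, Mat2a, Nr4a2 and Nr4a3, which the rule takes. A few genes that the rule takes are not reported here.

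The steps were tested on simulated counts drawn with the means and library sizes of these libraries. Their spread was the negative binomial dispersion of the main fit (a median coefficient of variation of 4.1%). The further spread of single genes that the fit also estimates was left out. For CpdA against medium (13360 simulated genes tested), 55.4% of genes changed 1.25-fold, 80.3% of those changed 1.5-fold and 92.2% of those changed 2-fold were recovered, and 9 of 13165 unchanged genes were called. In a second simulation of 13382 genes with the G2/M list shifted by 0.2, the preset, the estimated correlation and fry each called that list and 0 of the other 27. The simulated genes were drawn independently, whereas estimated correlations in the real lists reached 0.56 (hypoxia response). The simulation therefore cannot show how often the preset calls lists wrongly in these data.

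Alternatives planned before the data were examined were other scalings (DESeq2 size factors or library size alone), DESeq2 1.42.0, limma-voom, no count filter or a CPM of at least 5 in 3 libraries, an adjusted p under 0.01, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Removal of per-library trends on GC content and gene length (loess, span 0.5) was added after the data were seen; a GC value was found for 99.4% of tested genes. The table holds no fold changes or p-values of the authors, so none were compared. Of 108 marker entries 91 were found, and 3 list entries were matched by gene identifier to an older symbol.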

Results

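The libraries measured gene expression in mouse spleen CD4+ T cells activated for 2 days through CD3 and CD28, the antigen receptor and co-stimulatory signals of T cells. One group of 3 libraries had medium alone and the other group of 3 had CpdA, described in the series' design as an agonist of Gpr120. Gpr120 is the product of Ffar4, a receptor for long-chain fatty acids. The question the design states is how gene expression differs with and without the agonist. Library totals were 20247761, 23640735 and 22859881 counts for medium and 21407172, 25952169 and 25203448 counts for CpdA. Within a group, each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 2.18 to 4.18, against 10.8 to 18.7 between groups. Nothing says that libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

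With CpdA, genes of ribosome biogenesis, DNA replication, the type I interferon response and protein folding in the endoplasmic reticulum were higher, as were the Th2 cytokine genes Il4 and Il13. Genes of the hypoxia response and glycolysis and cytotoxic effector genes, such as Nkg7 and Gzmb, were lower. The lists behind these statements passed camera at its preset correlation, and 0 of the 28 lists passed with a correlation estimated for each (lowest adjusted p = 0.0664 with an estimated correlation). Most shifts were small. Of 13507 genes tested, 4483 (33.2%) changed, 2231 higher and 2252 lower, and 89.1% of them changed by less than 1.5-fold. At least 2-fold changes were found for 152 genes, 29 higher and 123 lower. This count depended on the setting, with 82 genes under DESeq2 and 29 with a CPM of at least 5 in 3 libraries. Medium and CpdA values did not overlap for 43.9% of tested genes, where chance gives 10%. The first principal component held 44.8% of the variance and parted the groups.

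**Figure D1:**
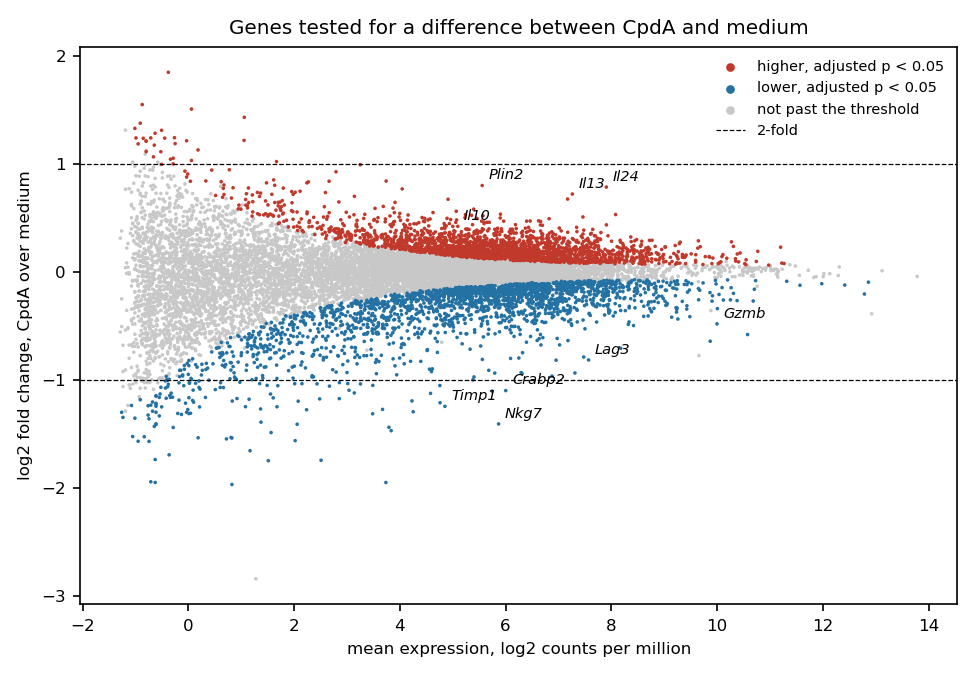
Log2 fold change of CpdA over medium against mean expression (log2 CPM) for the 13507 genes tested, 3 libraries per group. Red and blue points are genes past an adjusted p of 0.05, and dashed lines mark 2-fold; 123 of the 152 genes beyond those lines and past the threshold are lower with CpdA.

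The transcript of the receptor itself was near the limit of detection. Ffar4 (chromosome 19, 38097079 to 38114263, GRCm38) had 4 of 66748377 counts over the medium libraries and 0 of 72562789 over the CpdA libraries, which allows up to 0.0413 CPM. Ffar1, another receptor for free fatty acids, had 7 and 2 counts. A difference in either was not detectable at this depth. Of the 11 tested genes of the list for free fatty acid receptors and G protein signalling, 1 rose and 4 fell, among them the signal regulator Rgs16 (log2 fold change -0.67) and the arrestin gene Arrb1 (-0.49). Adjusted over the list alone, 2 rose and 4 fell, and the list was not called (adjusted p = 0.474), though it passed with fry, pointing down (0.0173).

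Among genes above the median expression, those that rose furthest included Plin2, Il24, Il13, Mat2a and Il4. Plin2, which codes for a coat protein of lipid droplets (chromosome 4, 86648386 to 86670060), rose from 33.9 ± 1.3 to 59.5 ± 1.2 CPM (SD, n = 3), a log2 fold change of 0.80 ± 0.05 (SE, adjusted p = 6.6e-16). Mat2a, an enzyme that makes S-adenosylmethionine, rose by 0.68 and Shmt1, an enzyme of one-carbon metabolism, by 0.54. Dgcr8, Grwd1, Heatr3 and Trim30d also rose, by 0.53 to 0.56; reads of Trim30d may be shared with its close relatives. The genes that fell furthest were Nkg7, a granule protein of cytotoxic cells, and Timp1, an inhibitor of matrix metalloproteases. Nkg7 (chromosome 7, 43437073 to 43438246) fell from 85.0 ± 2.0 to 32.2 ± 1.3 CPM (SD, n = 3), a log2 fold change of -1.41 ± 0.05 (SE, adjusted p = 2.6e-24). Timp1 changed by -1.25 and Crabp2, a binding protein for retinoic acid, by -1.10. Bzrap1, Myh10, Srgap3, Acvrl1, Nr4a3, Selenbp1, Plek and Gja1 also fell, with log2 fold changes from -1.21 to -0.94.

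**Figure D2:**
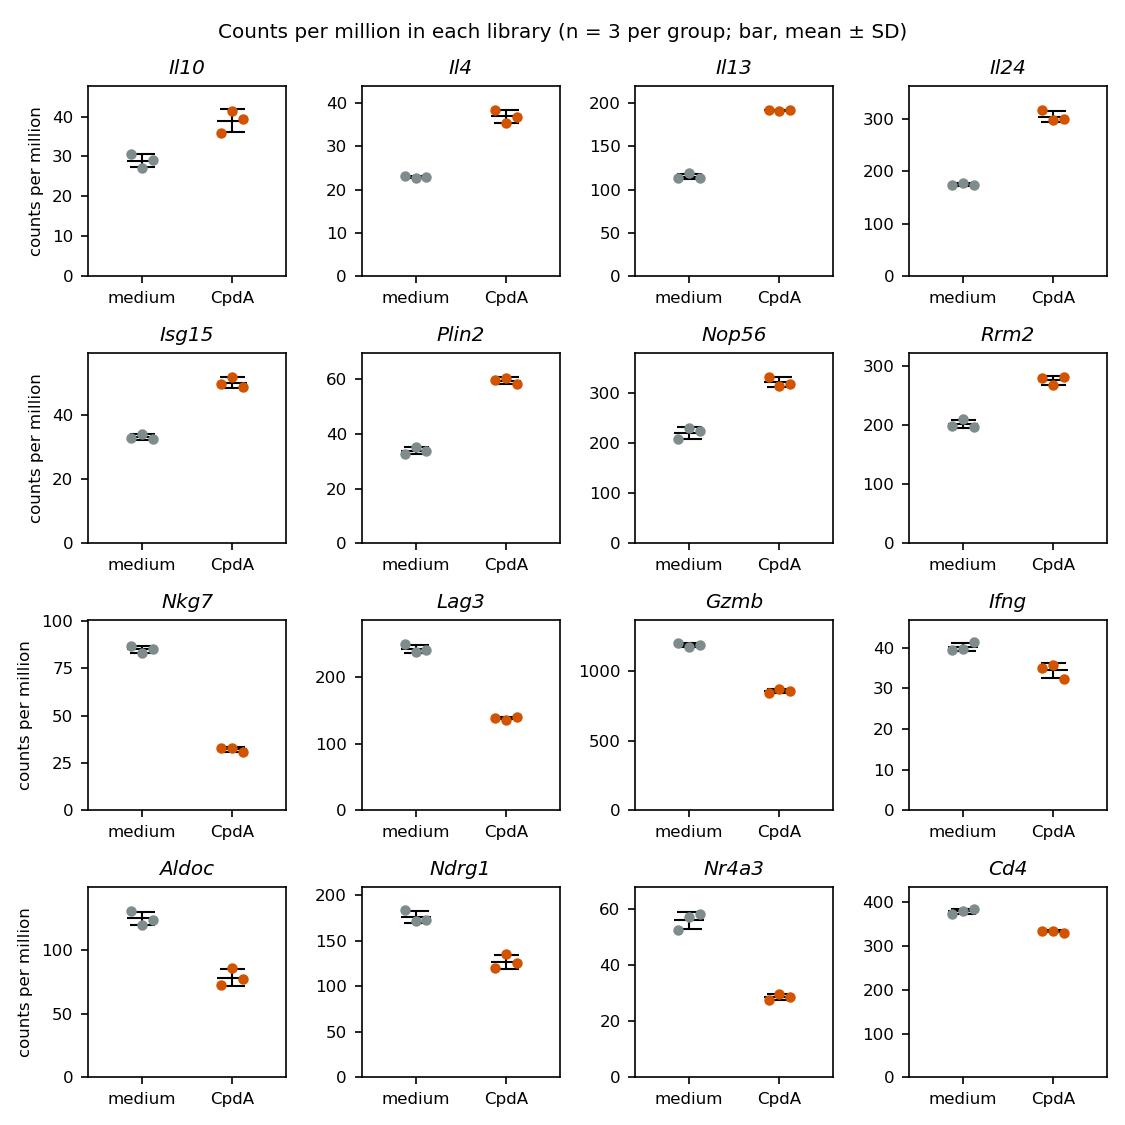
Level (CPM) of 16 genes in each library, medium in grey and CpdA in orange; points are the 3 libraries of a group and bars give mean ± SD. The medium and CpdA points do not overlap in any panel, as for Nkg7 (85.0 against 32.2 CPM) and Il13 (115.0 against 191.2 CPM).

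The Th2 list rose (adjusted p = 0.0306, camera), with 7 of 12 tested members higher and 2 lower, and the same numbers adjusted over the list alone. This call was not kept with an estimated correlation (adjusted p = 0.237 with an estimated correlation). The cytokine genes Il24, Il13 and Il4 rose by 0.79, 0.72 and 0.68, from 174.8, 115.0 and 22.9 CPM in medium. Il9 (0.62), Il6 (0.74) and Il5 (0.32) were also higher, whereas the receptor gene Il10ra (-0.32) and Nfil3 (-0.08) fell. Gata3, the regulator of Th2 differentiation, rose by 0.12 (adjusted p = 0.0045); without medium replicate 1 its log2 fold change was 0.09 and missed the threshold (adjusted p = 0.0603). The list, with a median log2 fold change of 0.22, lay close to the threshold: with 1 library fewer, adjusted p = 0.0555 without medium replicate 1, 0.0565 without medium replicate 3 and 0.0561 without CpdA replicate 2, while the call was kept without any 1 of the others. It was also lost with the stricter count filter (0.134), on ranks (0.119) and with GC and length trends removed (0.0628).

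The Th1 and cytotoxic effector list fell (adjusted p = 0.00652, camera; adjusted p = 0.147 with an estimated correlation). Of its 18 tested members 8 fell and 1 rose, or 9 and 1 adjusted over the list alone. Besides Nkg7, the granzyme gene Gzmb fell by 0.48 on the log2 scale, from 1187 to 856 CPM, and the perforin gene Prf1 by 0.84. Ifng, the main Th1 cytokine, fell by 0.23 (adjusted p = 0.00106), while Tnf rose by 0.30. Tbx21, the regulator of Th1 differentiation, had a log2 fold change of 0.02 (adjusted p = 0.791). Transcripts of CD8 T cells were few in both groups, with Cd8a and Cd8b1 summing to 8.31 ± 0.46 CPM in medium and 8.55 ± 1.08 CPM with CpdA (SD, n = 3; exact permutation p = 0.8, two-sided). NK cell markers summed to 54.1 and 50.8 CPM, mostly Gzma (51.9 and 49.1 CPM), and B cell markers to 111.4 and 115.4 CPM.

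The Tfh list also fell (adjusted p = 0.00652; adjusted p = 0.147 with an estimated correlation), with 8 of 15 members lower and 0 higher, the same numbers adjusted over the list alone. Btla and Pdcd1, inhibitory receptors, changed by -0.26 and -0.28, Sh2d1a, an adaptor of SLAM receptors, by -0.43, and the chemokine receptor Cxcr5 by -0.42. The changed members were 5 without CpdA replicate 1 or without CpdA replicate 2, and the list call was lost under the stricter count filter (adjusted p = 0.0553).

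Il10 (chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine gene, rose from 29.0 ± 1.7 to 39.0 ± 2.8 CPM (SD, n = 3), a log2 fold change of 0.42 (adjusted p = 5.2e-07). The IL-10 and co-inhibitory list did not pass (adjusted p = 0.0560; adjusted p = 0.257 with an estimated correlation): 2 of 20 members rose and 9 fell, also adjusted over the list alone. The inhibitory receptor genes Lag3 (-0.82), Ctla4 (-0.41) and Tigit (-0.32) fell, as did Ahr (-0.55). Prdm1 and Maf, regulators of Il10, had log2 fold changes of 0.08 and 0.06 (adjusted p = 0.382 and 0.237). Maf passed without medium replicate 1 (adjusted p = 0.0322) and with GC and length trends removed (0.0209). The list lay close to the threshold. It passed without CpdA replicate 2 (adjusted p = 0.0372), without a count filter (0.0425), with the stricter filter (0.0420), with limma-voom (0.0172), with GC and length trends removed (0.0206) and with fry (0.00275). Of 18 Treg members 2 rose and 9 fell, or 3 and 9 adjusted over the list alone, and the list did not pass (adjusted p = 0.0995), though it did with limma-voom (adjusted p = 0.0320) and fry (0.00155). Foxp3, the Treg regulator, had a log2 fold change of -0.09 (adjusted p = 0.551). In the Th17 list (adjusted p = 0.474) 3 of 13 members rose and 3 fell, also adjusted over the list alone, and Il17a, a Th17 cytokine gene, had a log2 fold change of -0.41 (adjusted p = 0.128).

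The type I interferon list rose (adjusted p = 7.3e-09, camera; adjusted p = 0.0664 with an estimated correlation). Of 27 members 18 rose and 1 fell, or 19 and 1 adjusted over the list alone. Isg15, a ubiquitin-like protein induced by interferon, rose by 0.58, Bst2, which tethers virus particles to the cell, by 0.29 and Trim30a by 0.35, though reads of the Trim30 family may be shared. Dhx58, a sensor of viral RNA, fell by 0.53.

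The lists of growth and division rose. In the MYC and ribosome biogenesis list (adjusted p = 3.6e-09, and adjusted p = 0.260 with an estimated correlation) 25 of 30 members rose and 1 fell, also adjusted over the list alone. Its nucleolar genes Nop56, Nop58 and Dkc1 rose by 0.53, 0.51 and 0.49. In the G1/S and DNA replication list (adjusted p = 1.2e-10, and adjusted p = 0.257 with an estimated correlation) 29 of 33 members rose and 0 fell, or 30 and 0 adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, rose by 0.44, Tyms, the thymidylate synthase gene, by 0.50 and Cdc6 by 0.47. In the G2/M list (adjusted p = 3.4e-05, and adjusted p = 0.256 with an estimated correlation) 18 of 32 members rose and 0 fell, or 21 and 1 adjusted over the list alone, with Ccnb1 and Birc5 at 0.31.

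The hypoxia response list fell (adjusted p = 3.6e-09; adjusted p = 0.260 with an estimated correlation), with 19 of 20 members lower and 0 higher, or 20 and 0 adjusted over the list alone. Ndrg1, a gene induced by hypoxia, fell by 0.48, from 176.0 to 126.8 CPM, P4ha2, a collagen prolyl hydroxylase, by 0.51 and Bnip3l by 0.41. The glycolysis list fell as well (adjusted p = 1.2e-06; adjusted p = 0.0781 with an estimated correlation), with 17 of 20 members lower and 1 higher, or 18 and 1 adjusted over the list alone. The aldolase gene Aldoc fell by 0.68, from 125.0 to 78.5 CPM, Pfkm, a phosphofructokinase, by 0.56 and Hk1, a hexokinase, by 0.33. Gapdh fell by 0.20; its many pseudogenes may share its reads. Slc16a1, a lactate transporter, rose by 0.21. Hk2 fell by 0.11 but was not past the threshold with GC and length trends removed (adjusted p = 0.0826), and the glucose transporter gene Slc2a1 had -0.05 (adjusted p = 0.222).

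The ATF4 and amino acid response list rose (adjusted p = 2.2e-05; adjusted p = 0.260 with an estimated correlation), with 19 of 28 members higher and 2 lower, or 21 and 2 adjusted over the list alone. Asns, the asparagine synthetase gene, rose by 0.27 and Slc7a3, an amino acid transporter, by 0.50, whereas Ddit4, also a hypoxia list member, fell by 0.34. The unfolded protein response list rose (adjusted p = 2.5e-06; adjusted p = 0.0781 with an estimated correlation), with 16 of 21 members higher and 0 lower, also adjusted over the list alone. The chaperone genes Hspa5 and Calr rose by 0.23 and 0.22. The cholesterol list rose (adjusted p = 0.00269; adjusted p = 0.147 with an estimated correlation), with 12 of 25 members higher and 1 lower, or 13 and 1 adjusted over the list alone. Insig1, a regulator of sterol synthesis, rose by 0.29 and Cyp51, an enzyme of the pathway, by 0.22, whereas Stard4 fell by 0.21.

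**Figure D3:**
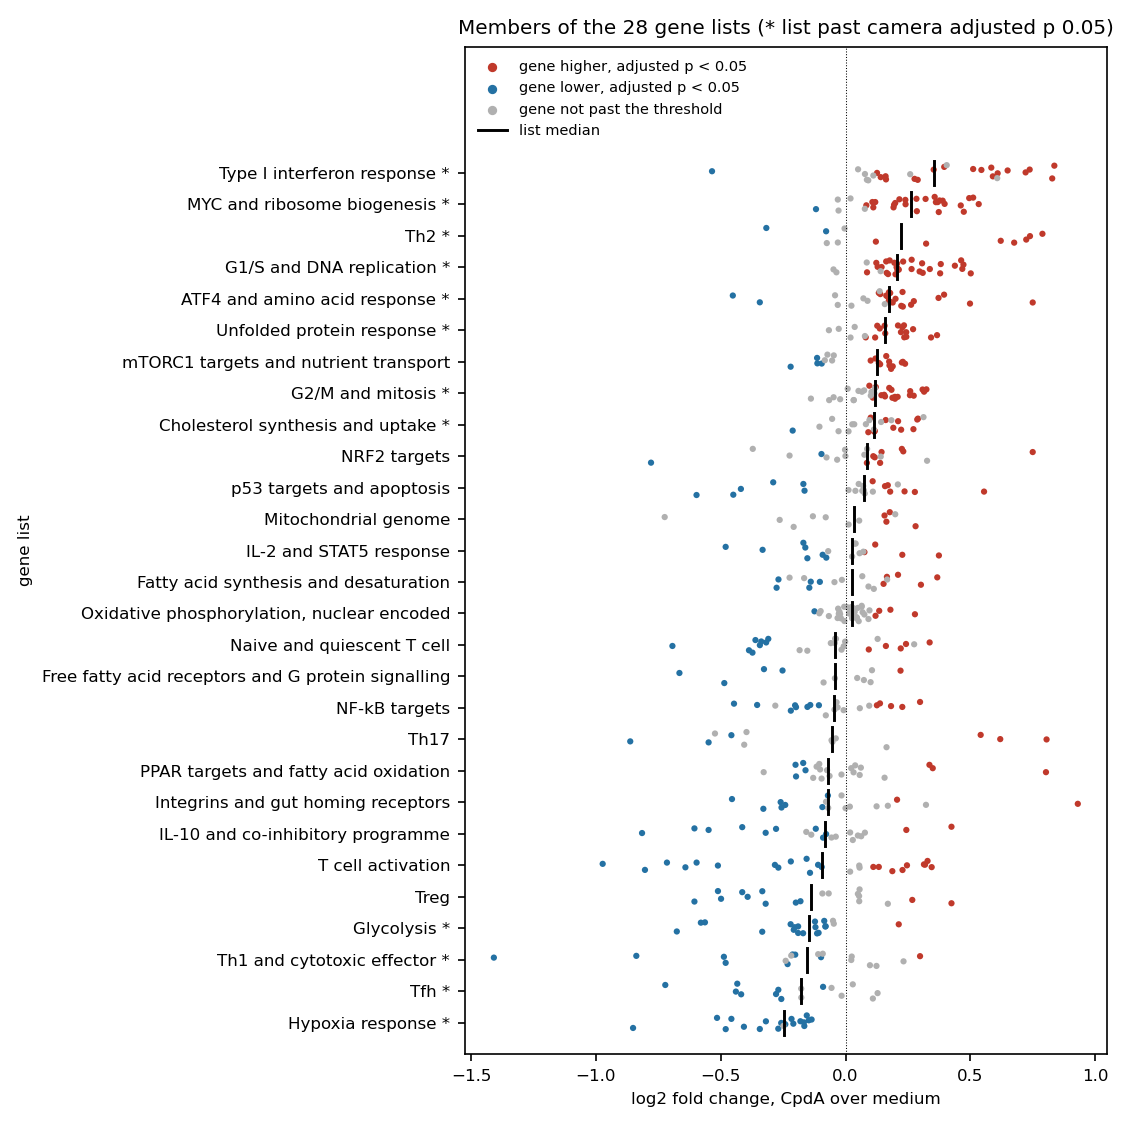
Log2 fold change of CpdA over medium for each tested member of the 28 lists, ordered by list median (black bar); red and blue members are past an adjusted p of 0.05. The 12 lists with an asterisk passed camera at its preset correlation, 8 higher and 4 lower, and 0 passed with an estimated correlation.

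The other lists did not pass and held members that went both ways. In the T cell activation list (adjusted p = 0.394) 9 of 25 members rose and 13 fell, or 10 and 13 adjusted over the list alone. Nr4a3 (-0.97), Nr4a2 (-0.72), Tnfrsf9 (-0.64) and Zbtb32 (-0.60) fell, and Il2 fell by 0.80 from 3.59 CPM. With fry, which asks another question, this list passed (adjusted p = 0.00155), as did the naive T cell (0.00217), IL-2 and STAT5 (0.00194) and integrin (0.0423) lists, all pointing down. In the naive T cell list (adjusted p = 0.135) 5 of 24 members rose and 8 fell, also adjusted over the list alone, with Ccr7, a homing receptor of naive cells, at -0.32. The PPAR and fatty acid oxidation list (adjusted p = 0.331) had 3 of 22 members higher and 4 lower, also adjusted over the list alone. Its transport gene Cpt1a rose by 0.35, while its median was -0.07, its mean 0.004 and its test pointed down. The fatty acid synthesis list (adjusted p = 0.966) had 5 of 18 members higher and 5 lower, also adjusted over the list alone, with Fasn at 0.30 and Scd2 at -0.27; its median, mean and camera test pointed up and its fry test down. The nuclear oxidative phosphorylation list (adjusted p = 0.227) had 4 of 37 members higher and 1 lower, also adjusted over the list alone. Its member Cyc1 rose by 0.13; it missed the threshold without medium replicate 1 (log2 fold change 0.08, adjusted p = 0.134) and without CpdA replicate 1 (0.11, adjusted p = 0.0601). Of 12 mitochondrial genes (adjusted p = 0.331) 4 rose and 0 fell, or 4 and 2 adjusted over the list alone, with mt-Nd1 at 0.28, a median of 0.03, a mean of -0.03 and a test that pointed up. The IL-2 and STAT5 list (adjusted p = 0.611) had 4 of 17 higher and 7 lower, or 6 and 8 adjusted over the list alone; its median was 0.03, its mean -0.03 and its test pointed down.

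In the mTORC1 list (adjusted p = 0.107) 12 of 20 members rose and 4 fell, also adjusted over the list alone, with the amino acid transporter genes Slc38a1 at 0.24 and Slc7a5 at 0.23. The list passed with GC and length trends removed (adjusted p = 0.0156), with limma-voom (0.0274) and with fry (0.00232). The NRF2 list (adjusted p = 0.179) had 8 of 20 higher and 2 lower, also adjusted over the list alone, with Txnrd1, a thioredoxin reductase, at 0.23. In the p53 list (adjusted p = 0.394) 7 of 22 members rose and 6 fell, or 8 and 6 adjusted over the list alone, with Trp53inp1 at -0.60 and Cdkn1a at -0.29. The NF-kB list (adjusted p = 0.348) had 5 of 21 higher and 8 lower, also adjusted over the list alone, with Ier3 at -0.45 and Ltb at -0.35. Of 17 integrin and homing genes (adjusted p = 0.331) 2 rose and 7 fell, or 3 and 7 adjusted over the list alone, with the chemokine receptor Cxcr4 at -0.45 and the integrin gene Itgb7 at -0.26.

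Of 14 CD4 T cell markers 8 fell and 2 rose, and their sum went from 4113 ± 47 to 3948 ± 54 CPM (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest this design allows). Cd4 fell by 0.20 and Cd3e by 0.27, and the receptor kinase gene Zap70 by 0.41, whereas Cd5 rose by 0.14. Dendritic cell markers summed to 254.2 and 239.9 CPM, mostly H2-Ab1, which fell by 0.37, and Cd74, which rose by 0.24. Macrophage markers summed to 10.1 and 10.2 CPM, plasma cell markers to 26.01 and 23.2, gamma delta T cell markers to 1.29 and 1.27 and platelet markers to 2.30 and 2.11 CPM. Neutrophil markers summed to 2.12 and 1.19 CPM, mostly Cxcr2 (1.98 and 1.08 CPM). Erythroid markers summed to 9.81 and 7.05 CPM, mostly Epor (8.06 and 5.62 CPM). Stromal and endothelial markers summed to 76.1 and 62.5 CPM, mostly Pecam1 (72.3 and 59.3 CPM), which T cells also express. After adjustment over the 12 lists the lowest exact p was 0.2. Mitochondrial counts made up 1.41% and 1.48% of the totals, ribosomal protein counts 12.2% and 12.4% and the 20 highest genes 10.5% and 10.0% (exact permutation p = 0.1, 0.3 and 0.1, two-sided). Medium and CpdA libraries did not overlap for the mitochondrial share and the 20 highest genes. Counts at rRNA loci were 0.90 ± 0.09% and 0.69 ± 0.13% (SD, n = 3; exact permutation p = 0.2, two-sided), with CpdA replicate 2 (0.84%) inside the range of the medium libraries.

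Changed genes also sorted by sequence. In the decile of lowest GC content 334 genes rose and 128 fell, and in the highest 117 rose and 309 fell; in the decile of longest genes 144 rose and 425 fell. This trend followed the groups: relative to the mean of the 6 libraries, the slope of expression on GC content was above 0 in all 3 medium libraries and below 0 in all 3 CpdA libraries. With both trends removed, 4460 genes were called, of which 3833 were among the 4483 and 3830 had the same direction.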

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

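Trend removal on GC content and length was the only setting chosen after the data were seen. The number of changed genes stayed within 1.5 times of 4483 under each alternative, from 3177 (adjusted p under 0.01) and 3448 (DESeq2) to 4538 (library size alone), and from 3660 to 4336 with 1 library left out. The 2-fold count of 152 moved to 29 with a CPM of at least 5 in 3 libraries (0 higher, 29 lower). It moved to 82 with DESeq2 (6 higher, 76 lower) and to 63 when tested against 1.5-fold (5 higher, 58 lower). The stricter filter tests fewer genes (9845); the cause was not tested for the others. With 1 library left out it ran from 140 to 206. Lists called numbered 12, between 11 and 15 under the other settings of camera or limma-voom. They were 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 20 with fry, which asks another question. The estimated correlation lay below the preset 0.01 for the interferon (-0.002), Th1 (-0.036), Tfh (-0.041), Th2 (-0.004) and cholesterol (0.009) lists. That argues against a higher correlation as the reason why these lists lost their call. It lay above 0.01 for the other lists called (0.013 to 0.56). The cause was not tested further. Of 134 tested named genes 129 kept their call and direction under each setting run, and 0 reversed; the exceptions were Cyc1, Gata3, Gnaq, Hk2 and Maf. Gnaq had an adjusted p of 0.0577 without medium replicate 1. The members called also moved for Th17 (2 under the stricter filter), Tfh (5 with DESeq2) and the fatty acid receptor list (3 without medium replicate 1). For oxidative phosphorylation they moved to 3 without CpdA replicate 1 and to 9 with trends removed, 4 higher and 5 lower. For the mitochondrial genome they moved to 7 with trends removed, 4 higher and 3 lower. As a mean of log values in place of a sum, marker differences changed sign for plasma cells (0.23), dendritic cells (0.005) and stroma (0.15), and moved for CD4 T cells (-0.10), gamma delta T cells (-0.44), NK cells (-0.32), macrophages (0.24), neutrophils (-0.22) and erythroid cells (-0.09). Genes with few counts limit these sums and the 2-fold calls.

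With the replicate number as a block, 3936 genes, 136 genes at 2-fold and 12 lists were called. Same-numbered libraries did not deviate together (correlations of -0.02, -0.01 and -0.00056 across genes). Above a log2 CPM of 5 the values were -0.26, -0.40 and -0.08, against -0.08 to 0.32 for different numbers. This check found no deviation shared by same-numbered libraries, and no library correlated best with its own number. It cannot exclude that the numbers pair the samples in another way. The second principal component (15.2% of the variance) put the numbers in the same order in both groups, which is a hint from the data and not from the design. On the first component the groups mirrored each other by number. Replicates 1, 2 and 3 lay at -21.3, -12.7 and -16.3 in medium and at 21.1, 12.4 and 16.7 with CpdA. The GC slopes mirrored by number too, in log2 per 10% GC. Replicates 1, 2 and 3 had 0.029, 0.051 and 0.024 in medium and -0.027, -0.054 and -0.023 with CpdA.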

Other observations

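The gene families of the next paragraph and the tests of low counts, of CD8 and NK cells and of activated and dividing cells were chosen after the results were seen; the tests of scaling and single libraries were not (the shift a scaling would need was worked out afterwards), and the tests of sequence trends use a setting added after the data were seen.

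Gene families that are not fixed lists, though some share members with them, are given beside the 33.2% of all tested genes that changed. Metallothionein genes, which bind metal ions, were lower in 3 of 3 cases (Mt2 -0.82, Mt1 -0.71, Mt3 -0.65), though reads of close copies may be shared. In one-carbon and nucleotide synthesis 16 of 18 genes rose and 1 fell, with Mat2a at 0.68, Umps at 0.38 and Ppat at 0.34 (adjusted p = 0.231 with an estimated correlation). Of 14 proteasome core genes 12 rose and 0 fell, with Psma1 at 0.21 (adjusted p = 0.214 with an estimated correlation). All 6 tested hosts of small nucleolar RNAs rose, Snhg4 by 0.49 and Gas5 by 0.23 (adjusted p = 0.152 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases 10 rose and 1 fell, with Lars at 0.29 (adjusted p = 0.231 with an estimated correlation), and of 14 actin and myosin genes 8 fell and 1 rose, with Espn at -0.79 (adjusted p = 0.152 with an estimated correlation). Of 8 chaperonin genes 3 rose and 0 fell (adjusted p = 0.0484 at the preset correlation and 0.366 with an estimated correlation), and of 5 polyamine genes 3 rose and 0 fell, with Amd1 at 0.44 (adjusted p = 0.0719 at the preset correlation and 0.290 with an estimated correlation). At the preset correlation camera gave the one-carbon, proteasome, small nucleolar RNA host, synthetase and actin families adjusted p from 8.7e-07 to 0.00213. These families were picked from the same results and adjusted only over the families tested. Their p-values are therefore descriptive and cannot stand beside those of the fixed lists. The Nr4a receptors Nr4a3, Nr4a2 and Nr4a1 all fell.

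Of the 152 genes changed at least 2-fold, 80.9% were lower with CpdA. Sequence bias as the whole cause is argued against, with 82.1% lower after GC and length trends were removed, but the scaling of libraries stays open: 2 other scalings left at least 78.9% lower, yet moved the median gene by at most 0.009 on the log2 scale, where a shift of about 0.14 would be needed to bring the share to 60%. Low counts were tested in 3 ways: the first, on the 7 genes above the median expression (all lower, 100%, exact 95% interval 59.0 to 100%), left the matter undecided, the 1.5-fold test was picked next, and the stricter filter last, when its counts were already known. With a CPM of at least 5 in 3 libraries all 29 calls were lower (100%, interval 88.1 to 100%). Of 1.5-fold calls above the median expression 47 of 52 were lower (90.4%, interval 79.0 to 96.8%). Lower calls thus also prevailed among genes at those levels. Because both tests were picked after the first was undecided, they cannot decide whether low counts are the cause. Of the 152 genes, 145 did not lie above the median expression, 116 of them lower and 29 higher. Among all tested genes the median log2 fold change was also lower at low expression. It was -0.105, -0.064, -0.042 and -0.018 in expression deciles 1 to 4 (lowest first), against 0.015 to 0.031 in deciles 5 to 10. Whether scaling or low counts gave this shift was not tested. Low counts stay open, and a response of the cells to CpdA stays open and untested.

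The lower cytotoxic effector genes had a median log2 fold change of -0.36 over the 8 that fell, and fewer cells of another type could lower them, although the samples are labelled as CD4+ T cells, with no method of isolation or purity given. Fewer CD8 T cells are argued against, since the log2 ratio of summed Cd8a and Cd8b1 was 0.058 ± 0.118 (SE). For NK cells the receptors gave -0.32 ± 0.18 (SE), from 145 and 126 counts; this SE is the counting error, used because the SE between libraries was smaller (0.14). Nkg7 and Prf1, picked because they fell furthest, lay below the receptors by 1.09 and 0.51 (the smaller gap is -0.51 ± 0.20, SE). Genes picked for their fall, set against so few counts, cannot decide whether NK cells were lost. For all 8 genes a smaller share of NK cells and lower expression within T cells cannot be told apart on these few counts. The levels are far apart, with Klrk1 at 1.28 CPM and Gzmb at 1187 CPM in medium, and Gzma did not pass (-0.09, adjusted p = 0.163).

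Hypoxia and glycolysis genes were lower together, by list tests that passed at the preset correlation but not with an estimated one (adjusted p = 0.260 and 0.0781 with an estimated correlation). Sequence bias is argued against as the whole cause, since 94.4% of their 36 lower calls were left after trends were removed, and so is a single deviating library, since the highest adjusted p at the preset correlation with 1 library left out was 1.45e-05. The G1/S and MYC lists did not fall with these genes, and the lower of their medians was 0.21. That they were higher was known when this test was chosen. Neither list passed with an estimated correlation (adjusted p = 0.257 and 0.260, camera). List levels are also no count of dividing cells, so the test cannot decide whether fewer cells divided. Fewer activated cells stay open, because the T cell activation list had a median of -0.10 with 9 members higher and 13 lower, among the latter Nr4a3 and Il2. An effect of CpdA and differences in cell density or oxygen between cultures were not tested.

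With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave a count as large: 4483 changed genes against 0 in any other, 152 genes at 2-fold against 0, and 12 lists against at most 8. At an unadjusted p under 0.05, edgeR gave 5606 genes for the real split and 143 to 542 for the others. Each of the other splits keeps part of the difference between the groups, so its list count is no value for unchanged cells.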
